A study of Cereibacter sphaeroides 2.4.1 with 24 samples.

How the data were processed

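Transcript levels were measured on 1-colour oligonucleotide expression arrays hybridised with biotin-labelled cDNA from total RNA. The bacterium was Rhodobacter sphaeroides 2.4.1, listed today as Cereibacter sphaeroides. Per the labels, 4 independent cultures grown photosynthetically without oxygen were each sampled before the light was turned off and oxygen was admitted, and again at 15 and 30 min and at 1, 2 and 4 h after that. That gave 24 arrays in 6 groups of 4. For 3 of the 4 arrays taken before the shift, a free-text remark in the labels names an aerobic condition while the title and source name the sample as taken before the shift. The title and source were followed. The place of those arrays in a principal component analysis is given with the results.

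The deposited values were array intensity in linear units, a signal per probe set computed by the authors with MAS5, per the submitters' processing notes, in a version not stated. No detection call, background level, array date or genome build was stated. On the deposited intensity values, the mean after trimming 2% at each end was 250.1 on each of the 24 arrays, so each array had been scaled as a whole to a common trimmed mean. Such scaling fixes the average signal of an array, and a change in the total amount of mRNA per cell cannot be read from these values.

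Of 5355 probe sets, 3 control probe sets were left out. The 2 signals at or below zero were set to the lowest positive signal of their array, and log2 of the signal was taken. The dimmest 20% of the remaining 5352 probe sets, by mean log2 signal over the 24 arrays, were left out too, which set the limit at a geometric mean signal of 26.08 and kept 4281. The platform annotation named 1 gene symbol for 542 probe sets, several for 0 and none for 4813, so most probe sets could not be named. Of the kept probe sets, 502 had a name. Symbols were looked up in a RefSeq table of the organism for synonyms, which matched 535 named probe sets by symbol and 4 by synonym. No coordinates are given, because the build of the array is not stated. Where several probe sets carried 1 gene, the probe set with the highest mean signal stands for it, and the others are given where they differ. The annotation gave symbols without product names. Gene functions in the text are background knowledge attached to the symbol, and a symbol shared by 2 genes is given with its Entrez gene number.

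Each comparison was fitted with limma (version 3.58.1 in R 4.3.3), using lmFit and eBayes with an intensity trend on the log2 signals of all 24 arrays. The groups thus shared 1 estimate of the spread per probe set, with 18 residual degrees of freedom and 6.654 prior degrees of freedom. Tests were two-sided. Adjusted p-values are Benjamini-Hochberg values over the 4281 probe sets within a comparison, a probe set was called at an adjusted p under 0.05, and the number that also changed at least 2-fold is given beside each count. An F test over the 5 contrasts against before the shift counted the probe sets that changed at any time. Values in the text are means of signal with the SD of 4 arrays, and log2 changes with the SE from limma.

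Gene lists were fixed by symbol or product name before the data were examined, as were the design, the alternatives and the rule for named genes. Lists with at least 4 kept members were tested with limma's camera at a preset correlation of 0.01 between genes. Its p-values were adjusted by Benjamini-Hochberg over all lists and 6 comparisons, which were the 5 against before the shift and 4 h against 15 min. Beside each list stands the number of members called among all 4281 probe sets and the number called when adjusted over the list alone. Smaller lists are described by their members. List names were fixed in advance and can be wider than the members kept. The flagella and chemotaxis list held motA and flg, flh and fli genes, with no chemotaxis gene. The iron and manganese list held exbB, exbD, feoB and bfr genes, with no manganese gene. The oxidative stress list held msrA, trxA, trxB, grxC and gor, with no catalase or superoxide dismutase gene. The fixed rule named 87 genes. For 15 min and for 4 h against before the shift it took the 10 largest called rises and the 10 largest called falls with the same sign in all 4 cultures. It took the 3 largest of each for 30 min, 1 h and 2 h, and the largest 1 of each for the other comparisons. It also took the called member with the largest rise and fall of each list at 15 min and 4 h, and a set of regulators and photosynthesis genes chosen in advance. Patterns written for product names matched nothing, so a planned list of transposase and phage genes had no members. The fixed list of translation factors and tRNA synthetases sought the synthetases by product name, so it kept the factors alone. A further 17 lists, 1 of them for the synthetases, were chosen after the symbols and the data were seen. They are kept apart from the fixed ones.

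Per the labels, the samples of each culture were aliquots of 1 bottle, so the replicate number pairs the arrays across times. Deviations from the group means were checked for this. Over 60 pairs of arrays with the same number at different times, the correlation of deviations averaged 0.078 (range -0.17 to 0.34, 24 of them above 0.1), and over 180 pairs with different numbers it averaged -0.026 (range -0.3 to 0.24, 11 above 0.1). The fit without culture as a block was fixed as the main one, and the blocked fit was run as an alternative.

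Before use, the fit was tested on simulated data made from the 4281 probe sets for 15 min against before the shift. Of 67 genes changed by 0.5 on the log2 scale it called 22 (32.8%), of 67 changed by 1 it called 49 (73.1%), and of 66 changed by 2 it called 62 (93.9%), all with the right sign. Of 140 calls, 7 (5%) were of unchanged genes. The list test called the 1 shifted list among 51 lists of 10 genes and 0 of the others. In this simulation noise was independent between probe sets and most probe sets were unchanged, unlike in the real data. Real lists hold genes that vary together (estimated correlation up to 0.5), so the list test was not checked for such lists. The number of arrays limits the precision of every value.

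The alternatives were the culture number as a fixed or a random block, quantile normalization, median centring, a pseudocount of 10.3 (the 10th percentile of the signals), no filter or a 40% filter on dim probe sets, eBayes without the trend or robust, and only the 8 arrays compared. Leaving out each culture and each single array was tried as well. For lists they were an estimated correlation between genes, limma's fry, the block, both scalings, no filter and each culture left out. Other splits of the 8 arrays of a comparison were refitted too, 35 in each case, and 100 for the F test.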

Results

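Transcript levels were measured in Rhodobacter sphaeroides 2.4.1, a purple bacterium that lives by photosynthesis in light without oxygen and by respiration when oxygen is present. The same 4 cultures were followed from anaerobic photosynthesis into darkness with oxygen, and the design asks how the transcriptome moves between these states. Each later time set against before the shift answers how far it has moved, each time set against the one before it answers when genes move, and 4 h set against 15 min answers which changes last. Each of the 6 groups held 4 arrays, from before the shift and from 5 times after it. Light was removed and oxygen added at the same moment, so no comparison here separates the effects of the 2, and no culture was kept in the light as a control for time. Within groups, the log2 signals of 2 arrays correlated with r of 0.9355 to 0.9739 across probe sets, which are not independent replicates. The first principal component (44.4% of the variance) parted the 4 arrays before the shift, at -62.6 to -61.1, from all later arrays, at 2.1 to 18.4. The second (21.6%) ordered the later groups by time. The median log2 signal of the kept probe sets moved against before the shift by -0.19 at 15 min, -0.09 at 30 min, 0.01 at 1 h, 0.09 at 2 h and 0.13 at 4 h, and all changes are given on the scale the authors set.

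In limma's F test with Benjamini-Hochberg adjustment, 3016 of 4281 probe sets (70.5%) changed over the 6 times. Against before the shift, 954 probe sets rose and 1334 fell at 15 min, 1049 and 1119 at 30 min, 1165 and 961 at 1 h, 1368 and 813 at 2 h, and 1520 and 680 at 4 h. Of the 479 named genes kept, by the brightest probe set of each, 189 rose and 128 fell at 15 min, and 256 and 79 at 4 h. The lists hold named genes only but are tested against all kept probe sets. A rise of a list can thus be shared by named genes at large.

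**Figure D1:**
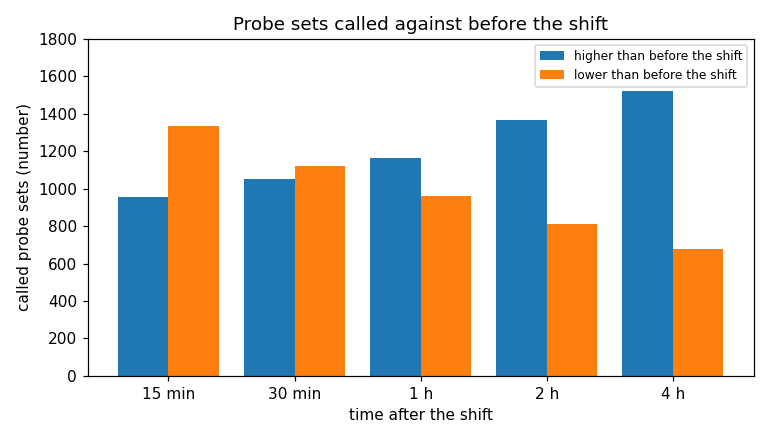
Number of probe sets called against before the shift (y axis, count) at each later time (x axis), with 1 bar for those higher and 1 for those lower. Higher calls went from 954 at 15 min to 1520 at 4 h and lower calls from 1334 to 680; the excess of lower calls turned at 15 min when arrays were median centred (45.5% lower) or quantile normalized (48.4%), and so it did at 30 min (45.4% and 46.9%).

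At 15 min, transcripts for synthesis of the photosynthetic pigments had collapsed. Taking the brightest probe set of each named gene, the largest fall was that of pufQ (Entrez gene 3719269), the first gene of the operon for the reaction centre and the LH1 antenna, from a signal of 6400 ± 502 (SD, n = 4) to 76.6 ± 15.6, a log2 change of -6.40 ± 0.16 (SE, adjusted p = 8.6e-21). bchE (3719193), the oxygen-independent cyclase of bacteriochlorophyll synthesis, fell from 2540 ± 123 to 31.4 ± 3.1, and crtA (3719281), the spheroidene monooxygenase of carotenoid synthesis, from 5460 ± 296 to 111 ± 24.3. In the same 15 min the chaperone gene clpB (3718495) rose from 157 ± 18.3 to 2710 ± 456, a log2 change of 4.11 ± 0.22 (adjusted p = 1.4e-14). The iron-sulfur cluster assembly genes sufB (3718814) and sufC (3718812) rose 12.6-fold and 13.2-fold, to 5690 ± 497 and 5760 ± 385.

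All 11 measured genes of bacteriochlorophyll and carotenoid synthesis fell at 15 min (11 adjusted over the list alone), with a median log2 change of -4.57 (camera adjusted p = 2.4e-09). Among them bchF, bchC and bchI fell by 52.5-fold, 33.4-fold and 29.5-fold, with bchC dim at 15 min (20.7) and its log2 change, -5.06, at -4.37 with a pseudocount. The other probe sets for bchF went as low as -8.58. Of the photosynthetic complexes, 7 of 7 members fell (7 adjusted over the list alone; median -1.99, adjusted p = 3e-05). They fell unevenly: pufL and pufM, the reaction centre L and M subunits, fell by 1.89 and 1.99 on the log2 scale and puhA, the H subunit, by 1.52. For pufA, the LH1 alpha polypeptide of the same operon, the change was -0.30 ± 0.10 (adjusted p = 0.019), from 12100 ± 1380 to 9880 ± 1290. That call ended with quantile normalization (-0.10, adjusted p = 0.27), with median centring (-0.11, 0.47) and without single arrays or cultures (adjusted p up to 0.098, without culture 2), over a range of 0.0028 to 0.47 for all alternatives.

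In heme synthesis hemA (3720398), the 5-aminolevulinate synthase that starts the pathway, fell from 5510 ± 294 to 332 ± 61.1, and hemN, an oxygen-independent coproporphyrinogen oxidase, fell by 5.36 on the log2 scale, while hemF (3718332), the oxygen-dependent enzyme for that step, rose 2.97-fold. In all, 5 of the 7 heme genes fell and 2 rose, the other rise being that of hemH, the ferrochelatase, at 0.68, named here after its value was seen (5 and 2 adjusted over the list alone; median -2.58, adjusted p = 0.0085). The isoprenoid and quinone list fell in 7 of 7 members (7 adjusted over the list alone; median -1.16, adjusted p = 6e-05), led by dxs, the first enzyme of isoprenoid synthesis, at -2.23. cbbX, the Rubisco activase and the single member measured for the Calvin cycle, fell by 3.88 on the log2 scale. The 3 measured genes of the cbb3 oxidase, the terminal oxidase with high affinity for oxygen, fell too (3 adjusted over the list alone; median -0.99), with ccoO at -1.10 and ccoN at -0.94. Of the single regulators named, tspO fell by 3.92, appA by 3.35, ppsR by 0.75 and the anaerobic regulator fnrL by 0.65 on the log2 scale. Over the 5 probe sets of each, the changes were -3.35 to -3.01 for appA, -1.11 to -0.75 for ppsR and -0.67 to -0.52 for fnrL. dksA, which modulates RNA polymerase, fell by 4.13.

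Of 10 heat shock proteins and proteases, 7 rose and 1 fell at 15 min (7 and 1 adjusted over the list alone; median 1.5, adjusted p = 0.00013). dnaK and dnaJ rose 8.16-fold and 8.70-fold and a groEL copy (3719842) 3.43-fold, while clpX fell by 0.65 on the log2 scale. All 9 measured subunits of NADH dehydrogenase, complex I of respiration, rose (9 adjusted over the list alone; median 1.43, adjusted p = 3.4e-08), with nuoN up 3.13-fold. Of 45 ribosomal proteins, 40 rose and 1 fell (40 and 1 adjusted over the list alone; median 0.90, adjusted p = 5.1e-15). The ribosomal call was lost at adjusted p = 0.061 with an estimated correlation, the highest of its alternatives (lowest 1.1e-17). exbB and exbD, which energise uptake across the outer membrane, rose 9.05-fold and 9.21-fold. uxaC and kduI, named for sugar acid breakdown, rose 15.0-fold and 12.8-fold. pqqD, of PQQ cofactor synthesis, rose 5.39-fold and phaC, the polyhydroxyalkanoate synthase and the single member measured of its list, 4.53-fold. msrA, a repair enzyme for oxidised methionine, rose 2.66-fold and the DNA repair gene uvrA 2.78-fold. chrR, the anti-sigma factor of the singlet oxygen response, rose 4.40-fold. The change of the probe set annotated rpoE, whose match to the sigma factor bound by ChrR is uncertain, was -0.58 (adjusted p = 0.079).

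Genes of the remaining lists went both ways or passed the test singly at 15 min. In the iron and manganese list 3 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.18), the falls being feoB, of ferrous iron uptake, at -1.60 and a bacterioferritin gene (bfr, 3722043) at -1.68. The 2 genes of an ATP synthase operon rose and the 2 of another fell (2 and 2 adjusted over the list alone; adjusted p = 0.8), with atpA (3719828) at 0.60 and atpD (4796502) at -2.45. In the citric acid cycle 3 rose and 3 fell of 7 (3 and 3; adjusted p = 0.99), with fumC (3719607) at 0.93 and sdhA (3720729) at -0.97. Of 4 cytochrome genes 1 rose, ccmD of cytochrome c maturation at 0.58, and 1 fell, cycA for cytochrome c2 at -1.39 (1 and 1; adjusted p = 0.93). Of 8 translation factors 3 rose and 1 fell (3 and 1; adjusted p = 0.54), the elongation factor gene tsf at 0.85 and fusA at -3.03. Of 5 oxidative stress genes 2 rose (2; adjusted p = 0.17). Of 11 cobalamin genes 4 fell (2 adjusted over the list alone; adjusted p = 0.36), cobO at -1.42 among them. Of 4 hydrogenase maturation genes 1 fell (1; adjusted p = 0.75), and of 16 DNA repair genes 3 rose and 6 fell (3 and 6; adjusted p = 0.98). Of the 19 genes of the flagella and chemotaxis list, all flagellar by symbol, 7 fell (6 adjusted over the list alone, and 11 with culture as a block; adjusted p = 0.3), fliN of the motor switch at -2.18 among them. Of 3 nitrogen fixation genes 1 rose and 1, the activator gene nifA, fell by 1.10 (1 and 1 adjusted over the list alone), and of the 2 regulators of anaerobic reductases 1 rose and 1 fell (1 and 1).

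At 15 min, 53.4% of probe sets were called, 453 with a rise and 550 with a fall of at least 2-fold. Falls made up 58.3% of the calls, and 45.5% after median centring or 48.4% after quantile normalization. Among probe sets without a gene name, number 3298 had the largest rise, 7.68 ± 0.33 on the log2 scale (adjusted p = 1.9e-16), and number 2186 the largest fall, -6.49 ± 0.38 (adjusted p = 7.3e-14).

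**Figure D2:**
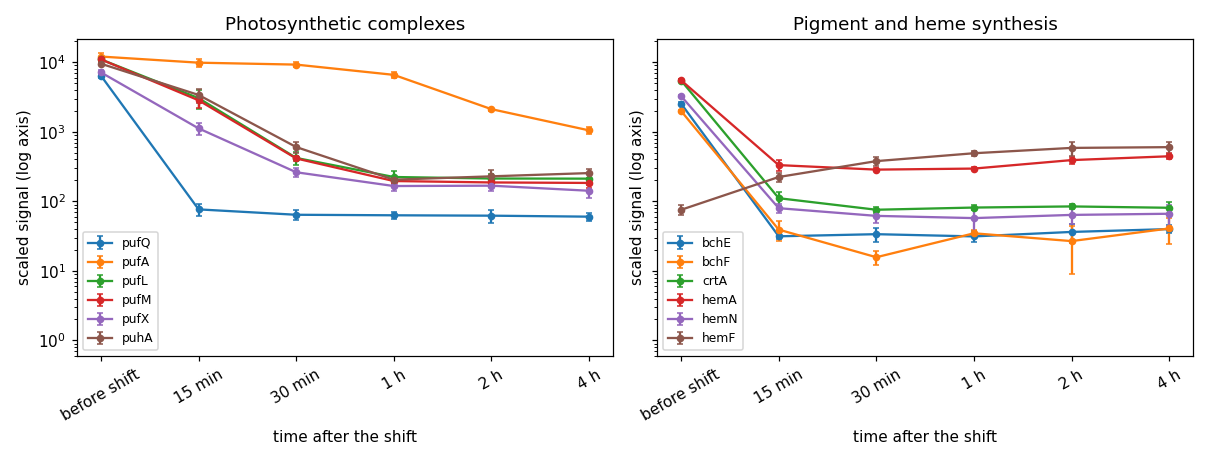
Scaled signal (y axis, log scale) by time after the shift (x axis) for 6 genes of the photosynthetic complexes (left) and 6 of pigment and heme synthesis (right); points are means and bars the SD of 4 arrays. pufQ was at 76.6 by 15 min, pufL and pufM were at 224 and 196 by 1 h, pufA was at 9880 at 15 min and at 1050 by 4 h, and hemF went from 75.6 to 602.

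At 30 min the reaction centre transcripts had followed the pigment genes down. pufL stood at 421 ± 84, a log2 change of -4.72 ± 0.19 against before the shift (adjusted p = 3.7e-17), pufM at 414 ± 31.2 and puhA at 604 ± 110. Among the largest named falls were those of bchF, pufQ and bchE at -7.01 (-6.27 with a pseudocount, its signal being down to 15.7), -6.65 and -6.26, and the largest named rises those of uxaC, sufC and kduI at 3.88, 3.74 and 3.72. pufA was still at 9270 ± 789 (-0.38, adjusted p = 0.0032).

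The photosynthetic complexes fell in 7 of 7 members at 30 min (7 adjusted over the list alone; median -4.72, adjusted p = 3.9e-08), pigment synthesis in 11 of 11 (11; median -4.66, adjusted p = 2e-10), isoprenoid and quinone in 7 of 7 (7; median -1.11, adjusted p = 6e-05), and heme synthesis in 5 of 7 with 2 rises (5 and 2; median -2.62, adjusted p = 0.005). NADH dehydrogenase rose in 9 of 9 (9; median 1.51, adjusted p = 6.5e-08). Ribosomal proteins rose in 41 of 45 with 1 fall (41 and 1 adjusted over the list alone; median 0.86, adjusted p = 6.2e-15), but with an adjusted p = 0.063 with an estimated correlation (lowest of the alternatives 1.1e-17). Heat shock genes rose in 6 of 10 with 2 falls (6 and 2; median 0.76, adjusted p = 0.0042), but with an adjusted p = 0.14 with an estimated correlation (lowest 2.6e-11). dnaK stood at 4160 ± 958 and clpB at 1210 ± 418. The other lists did not pass the test, the lowest being translation factors at adjusted p = 0.17 and cobalamin at 0.18. Of 19 flagellar genes 1 rose (0 adjusted over the list alone) and, with culture as a block, 8 rose. Calls covered 50.6% of probe sets, with 438 rises and 460 falls of at least 2-fold. Falls made up 51.6% of the calls, and 45.4% after median centring or 46.9% after quantile normalization.

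At 1 h the chaperone transcripts had come down while reaction centre transcripts were still being lost. The mean of the pigment synthesis list fell no further, at -4.68 at 30 min and -4.56 at 1 h on the log2 scale. clpB stood at 101 ± 20.1, below its level before the shift (-0.65 ± 0.22, adjusted p = 0.016), and dnaJ at 300 ± 52.6 no longer passed the test (0.38, adjusted p = 0.089). pufL, pufM and puhA reached 224 ± 51.2, 196 ± 14.8 and 205 ± 21.3. ugpA (3721889), of glycerol 3-phosphate uptake, joined kduI and uxaC as the largest named rises, at 3.23, 3.82 and 3.70. pufQ, bchE and crtA were among the largest named falls at -6.67, -6.36 and -6.07.

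At 1 h the photosynthetic complexes fell in 7 of 7 members (7 adjusted over the list alone; median -5.55, adjusted p = 5.5e-10), pigment synthesis in 11 of 11 (11; median -4.41, adjusted p = 3.1e-11), isoprenoid and quinone in 7 of 7 (7; median -0.82, adjusted p = 0.00015) and heme synthesis in 5 of 7 with 2 rises (5 and 2; median -2.58, adjusted p = 0.0033). NADH dehydrogenase rose in 9 of 9 (9; median 1.5, adjusted p = 7.4e-08). Ribosomal proteins rose in 40 of 45 with 1 fall (41 and 1 adjusted over the list alone; median 0.76, adjusted p = 1e-11), with an adjusted p = 0.12 with an estimated correlation (lowest of the alternatives 4.1e-14). Of the 10 heat shock genes 2 rose and 3 fell (2 and 3; adjusted p = 0.95). Calls covered 49.7% of probe sets, with 485 rises and 412 falls of at least 2-fold.

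At 2 h, 2 genes of glycerol 3-phosphate uptake had the largest named rises, by the brightest probe set of each gene and among calls with the same sign in all 4 cultures. ugpA and ugpB (3721890) stood at 569 ± 66.8 and 1710 ± 64.7, log2 changes of 3.64 ± 0.17 (adjusted p = 9.6e-16) and 3.57 ± 0.14 (adjusted p = 2e-17), and kduI at 2.96. pufA was down by then too, at 2120 ± 116 (-2.51, adjusted p = 1e-16). pufQ, bchF and bchE were among the largest named falls at -6.71, -6.65 (-5.91 with a pseudocount) and -6.18. Flagellar transcripts were low: 11 of 19 fell and 0 rose (11 adjusted over the list alone, 13 with culture as a block; median -1.27, adjusted p = 0.005), flgG of the rod at -1.79 and fliN at -2.14 among them. With an estimated correlation that call was lost (adjusted p = 0.6 with an estimated correlation, 0.00022 with culture as a block).

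At 2 h the photosynthetic complexes fell in 7 of 7 members (7 adjusted over the list alone; median -5.42, adjusted p = 1.1e-11), pigment synthesis in 11 of 11 (11; median -4.09, adjusted p = 4.8e-12), isoprenoid and quinone in 6 of 7 (6; median -0.67, adjusted p = 0.00014) and heme synthesis in 5 of 7 with 2 rises (5 and 2; median -2.44, adjusted p = 0.0016). NADH dehydrogenase rose in 9 of 9 (9; median 1.63, adjusted p = 1e-07). Ribosomal proteins rose in 41 of 45 with 1 fall (41 and 1; median 0.69, adjusted p = 1.7e-08), with an adjusted p = 0.23 with an estimated correlation (lowest of the alternatives 7.2e-13). Calls covered 50.9% of probe sets, with 521 rises and 426 falls of at least 2-fold.

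At 4 h photosynthesis transcripts were still low, and genes of glycerol 3-phosphate uptake and of glycerol use were among the largest named rises. pufQ, crtA and bchE stood at 60.2 ± 7.89, 80.8 ± 15.8 and 39.9 ± 5.15, log2 changes of -6.74, -6.10 and -6.00, and pufM at -5.92 ± 0.14 (adjusted p = 8.2e-22). pufA had fallen 11.6-fold to 1050 ± 105. ugpA, ugpB and ugpE rose 9.74-fold, 9.49-fold and 3.94-fold, and glpD and glpK, the dehydrogenase and kinase of glycerol use, 3.91-fold and 3.79-fold. hemF reached 602 ± 123, a log2 change of 2.98 ± 0.16 (adjusted p = 2e-14).

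At 4 h the photosynthetic complexes fell in 7 of 7 members (7 adjusted over the list alone; median -5.67, adjusted p = 5.1e-13) and pigment synthesis in 11 of 11 (11; median -3.98, adjusted p = 5.3e-13). Heme synthesis fell in 5 of 7 with 2 rises (5 and 2; median -2.14, adjusted p = 8e-04), with hemN at -5.67 and hemA at -3.63. The isoprenoid and quinone list fell in 6 of 7 members (7 adjusted over the list alone; median -0.73, adjusted p = 2.3e-05). Among the named falls were tspO at -4.83, dksA at -4.51, bchF at -5.69, pufL at -5.71, pufX at -5.67 and puhA at -5.23. cbbX was at -3.12, the 3 cbb3 oxidase genes had a median of -0.71 with 3 falls (3 adjusted over the list alone), and appA was at -2.48. The change of fnrL was -0.20 (adjusted p = 0.04), with its 5 probe sets between -0.31 and -0.18. That call was lost without cultures 1, 2 or 3 (adjusted p = 0.1, 0.11 and 0.21) and without 1 of 7 single arrays (up to 0.11), over a range of 0.0018 to 0.21 for all alternatives. The change of ppsR was -0.18 (adjusted p = 0.31), with its 5 probe sets between -0.36 and -0.11.

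NADH dehydrogenase rose in 9 of 9 members at 4 h (9 adjusted over the list alone; median 1.59, adjusted p = 1.8e-07), nuoN 3.82-fold. edd, of the Entner-Doudoroff pathway, rose 4.45-fold, pcaD, named for aromatic compound breakdown, 4.51-fold, and phaC 3.72-fold. Ribosomal proteins rose in 38 of 45 with 3 falls (38 and 3 adjusted over the list alone; median 0.54, adjusted p = 2e-05), rplF and rpsP 2.00-fold and 2.03-fold. For that list the adjusted p = 0.43 with an estimated correlation (lowest of the alternatives 7.5e-12). Cobalamin genes fell in 6 of 11 with 1 rise (6 and 1 adjusted over the list alone; median -0.72, adjusted p = 0.045), cobW falling by 1.23 on the log2 scale and cobS rising by 0.72. The cobalamin call ended with an adjusted p = 0.46 with an estimated correlation and without culture 2 (0.067; lowest of the alternatives 0.0094). sufB and exbD were still 2.67-fold and 2.37-fold above their level before the shift.

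Other lists did not pass the test at 4 h. Flagellar genes fell in 2 of 19 members (0 adjusted over the list alone, 6 with culture as a block; median -0.54, adjusted p = 0.087), and the list passed with culture as a block (0.02) and without culture 2 (0.035), over a range of 0.02 to 0.81 for all alternatives. DNA repair genes rose in 8 of 16 (8; adjusted p = 0.25), recA and recQ at 0.63 and 1.02. Of 10 heat shock genes 2 rose and 3 fell (2 and 3; adjusted p = 0.54), clpB at -1.40 and the groEL copy (3719842) at 0.84. In the iron and manganese list 2 rose and 2 fell (2 and 2; adjusted p = 0.95), feoB at -2.71. In the ATP synthase list 2 rose and 2 fell (2 and 2; adjusted p = 0.74), atpA (3719828) at 0.95 and atpA (4796476) at -1.65. Of 7 citric acid cycle genes 3 rose and 2 fell (3 and 2; adjusted p = 0.89), mdh at 0.62 and sdhA (3720729) at -0.51. Of 4 cytochrome genes 1 rose and 1 fell (1 and 1; adjusted p = 0.74), cycA at -1.13. Of 8 translation factors 4 rose and 1 fell (4 and 1; adjusted p = 0.74), prfB at 0.92 and fusA at -2.52. Of 5 oxidative stress genes 1 rose and 2 fell (1 and 2; adjusted p = 0.74), gor at 0.51 and msrA at -0.43. Of 4 hydrogenase genes 1 rose and 1 fell (1 and 1; adjusted p = 0.91). nifA was at -1.38, and nifH, the nitrogenase reductase gene, at 0.10 (adjusted p = 0.79), with its sign turned by quantile normalization (-0.09) and median centring (-0.03). Of the 2 anaerobic reductase regulators 1 rose (1, with 1 fall, adjusted over the list alone), dorR at 1.10.

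Calls at 4 h covered 51.4% of probe sets, with 504 rises and 375 falls of at least 2-fold. Among probe sets without a gene name, number 3451 had the largest rise, 5.71 ± 0.30 (adjusted p = 1e-14), and number 1170 the largest fall, -6.78 ± 0.47 (adjusted p = 3.7e-12). The comparisons at 15 min and 4 h share their control arrays, which ties their changes together. Across probe sets their log2 changes correlated with r = 0.729, against 0.5 simulated with unchanged groups and 0.69 with the controls split between them. The covariance was 1.007, against 0.034 simulated, a difference of 0.973. Of the probe sets called, 750 rose at both times (338.7 for independent lists, 0 simulated, 622.7 with split controls) and 549 fell at both (211.9, 0.01 and 451). Another 32 rose at 15 min and fell at 4 h (151.5 for independent lists, 23.33 with split controls), and 187 fell first and then rose (473.6 and 130.5). The simulated groups were unchanged and gave almost no calls (on average 0.04 rises at 15 min and 0.01 at 4 h). Their overlap near 0 was thus fixed in advance and decides nothing. With split controls fewer arrays entered each comparison, and fewer rises were called (853.7 against 954 at 15 min, 1321 against 1520 at 4 h). The lower overlaps there therefore reflect fewer calls too.

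Between 15 and 30 min the reaction centre transcripts dropped again, and 11 of 19 flagellar genes rose and 0 fell (13 rose with culture as a block), with no list test made for this step. pufL had the largest named fall, from 3050 ± 909 to 421 ± 84 (-2.83 ± 0.19, adjusted p = 3.4e-11), and pufM, puhA and pufX fell by 2.75, 2.48 and 2.09 on the log2 scale. fliN rose from a dim 22.2 ± 19.4 to 101 ± 52.5 (2.43 ± 0.50, adjusted p = 0.0015; 1.83 with a pseudocount). clpB fell by 1.23 on the log2 scale and dnaJ by 0.78. In this step 286 probe sets rose and 177 fell, 74 and 52 of them at least 2-fold. Falls made up 38.2% of the calls, and 60.2% after median centring or 52.8% after quantile normalization. The 463 calls became 264, 303 and 251 without cultures 1, 2 and 3.

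Between 30 min and 1 h the chaperone transcripts clpB, dnaJ and dnaK dropped, with no list test made for this step. The mean of the heat shock list against before the shift went from 1.06 to 0.01. clpB fell 11.5-fold (-3.52 ± 0.22, adjusted p = 2.8e-11), the largest named fall, dnaJ 3.89-fold and dnaK 3.56-fold, while puhA fell by 1.55 on the log2 scale. The largest named rise was that of ugpA, from 253 ± 44.8 to 425 ± 37.1 (0.76 ± 0.17, adjusted p = 0.0043), a call lost without culture 3 (0.051; range over the alternatives 0.0012 to 0.051). In this step 207 probe sets rose and 192 fell, 16 and 57 of them at least 2-fold. Falls made up 48.1% of the calls, and 76.4% after median centring or 59% after quantile normalization. The 399 calls became 162, 240 and 160 without cultures 1, 2 and 3, and 254 without the 30 min array of culture 3.

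Between 1 and 2 h 9 of 19 flagellar genes fell and 0 rose (11 fell with culture as a block), with no list test made for this step, and pufA fell too. flgH, of the flagellar ring, fell from 55 ± 19.5 to 9.92 ± 9.02 (-2.76 ± 0.65, adjusted p = 0.0063), a call lost without culture 1 (0.078; range over the alternatives 0.00019 to 0.078). Its 2 h signal lies under the filter limit of 26.08, so the size is uncertain: -3.29 to -1.73 over the alternatives, the smallest with a pseudocount. flgG and fliN fell by 1.87 and 2.04 on the log2 scale. pufA fell 3.10-fold (-1.63, adjusted p = 1.1e-10), sufB 1.73-fold, exbB 1.90-fold and uxaC 2.04-fold. mscL, a mechanosensitive channel, had the largest named rise, from 202 ± 9.46 to 363 ± 45.8 (0.84 ± 0.13, adjusted p = 0.00011). In this step 194 probe sets rose and 165 fell, 14 and 93 of them at least 2-fold. Falls made up 46% of the calls, and 68.1% after median centring or 53.4% after quantile normalization. The 359 calls became 204 and 208 without cultures 1 and 3.

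Between 2 and 4 h kduI, exbB and sufB, which had risen at 15 min, fell. kduI had the largest named fall, from 566 ± 200 to 253 ± 63.9 (-1.12 ± 0.23, adjusted p = 0.0021), a call lost without culture 1 (0.075; range over the alternatives 1e-04 to 0.075). exbB, sufB and pufA fell by 0.99, 0.89 and 1.02 on the log2 scale. flgG had the largest named rise, from 67.2 ± 28.5 to 145 ± 50 (1.14 ± 0.35, adjusted p = 0.044). Its call was lost without cultures 1, 2 or 3 (0.2, 0.097 and 0.16), without single 2 h or 4 h arrays (up to 0.18, without the 2 h array of culture 2) and under other settings, over a range of 1.7e-05 with culture as a block to 0.2. In this step 132 probe sets rose and 172 fell, 24 and 67 of them at least 2-fold. The 304 calls became 175 and 177 without cultures 1 and 3.

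Set directly against 15 min, the 4 h arrays separated transient from lasting changes. clpB had the largest named fall, from 2710 ± 456 to 60.2 ± 12.4 (-5.50, adjusted p = 9.6e-17), and dnaK and dnaJ followed at -2.63 and -2.73. sufB, sufC, exbB and exbD fell by 2.24, 2.34, 2.34 and 1.96, and uxaC and kduI by 2.03 and 1.85. mscL had the largest named rise, from 121 ± 24.1 to 518 ± 48.9 (2.11 ± 0.13, adjusted p = 1.3e-12), and glpD and glpK rose by 2.03 and 1.93 on the log2 scale.

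Heat shock genes fell in 8 of 10 members from 15 min to 4 h, with 1 rise (8 and 1 adjusted over the list alone; median -1.18, adjusted p = 3.7e-09). The photosynthetic complexes fell in 5 of 7 (5; median -3.23, adjusted p = 1.3e-09), with pufM, pufL, puhA, pufA and pufX at -3.93, -3.81, -3.71, -3.23 and -2.98. The iron and manganese list fell in 4 of 5 with 1 rise (4 and 1; median -1.30, adjusted p = 0.0014), the rise being that of bfr (3722043) at 1.13. Oxidative stress genes fell in 3 of 5 with 1 rise (3 and 1; median -0.76, adjusted p = 0.032), msrA at -1.84 and gor at 0.50. That call ended with an adjusted p = 0.13 with an estimated correlation and without culture 3 (0.072; lowest of the alternatives 8.6e-06). Ribosomal proteins fell in 30 of 45 with 0 rises (33 adjusted over the list alone; median -0.32, adjusted p = 2e-11), against other genes, but the direction turned with quantile normalization (0.66), and the adjusted p = 0.13 with an estimated correlation (lowest of the alternatives 3.4e-13). Of the other lists, pigment synthesis (adjusted p = 0.92), heme synthesis (0.47), NADH dehydrogenase (0.75), isoprenoid and quinone (0.37) and DNA repair (0.22) did not pass. Their members did move: 2 of 11 pigment genes rose and 1 fell, 4 of 7 heme genes rose, and 3 of 9 NADH dehydrogenase genes rose. Of 7 isoprenoid and quinone genes 5 rose and 1 fell, and of 16 DNA repair genes 11 rose and 1 fell. Adjusted over the list alone, the rises were 2, 4, 3, 5 and 12, with the same falls.

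From 15 min to 4 h, 1664 probe sets rose and 528 fell, 430 and 261 of them at least 2-fold, so falls made up 24.1% of the calls, against 49.6% after median centring and 39.1% after quantile normalization. Some lists that did not pass had a median, a mean and a test direction of different signs. At 15 min these were the citric acid cycle (median -0.03, mean -0.04, test up but down with quantile normalization), the cytochromes (0.09, -0.16, up) and the translation factors (0.16, -0.08, up). At 4 h they were the citric acid cycle (0.26, 0.12, down but up with quantile normalization), the cytochromes (0.13, -0.11, down), the iron and manganese list (0.24, -0.19, down), oxidative stress (0.10, -0.04, down) and hydrogenase (0.24, 0.07, down). At 1 h the heat shock list (-0.07, 0.01, down) and the flagellar list (0.08, 0.04, down but up with either scaling) differed so. For 4 h against 15 min, pigment synthesis (0.52, 0.33, down but up with median centring), the flagellar list (0.37, 0.35, down but up with median centring), the citric acid cycle (0.33, 0.16, down but up with quantile normalization), the cytochromes (0.21, 0.04, down) and the translation factors (0.06, 0.14, down but up with quantile normalization) did. The cytochromes also differed at 30 min (0.11, -0.28, down), 1 h (0.09, -0.33, down) and 2 h (0.02, -0.21, down).

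**Figure D3:**
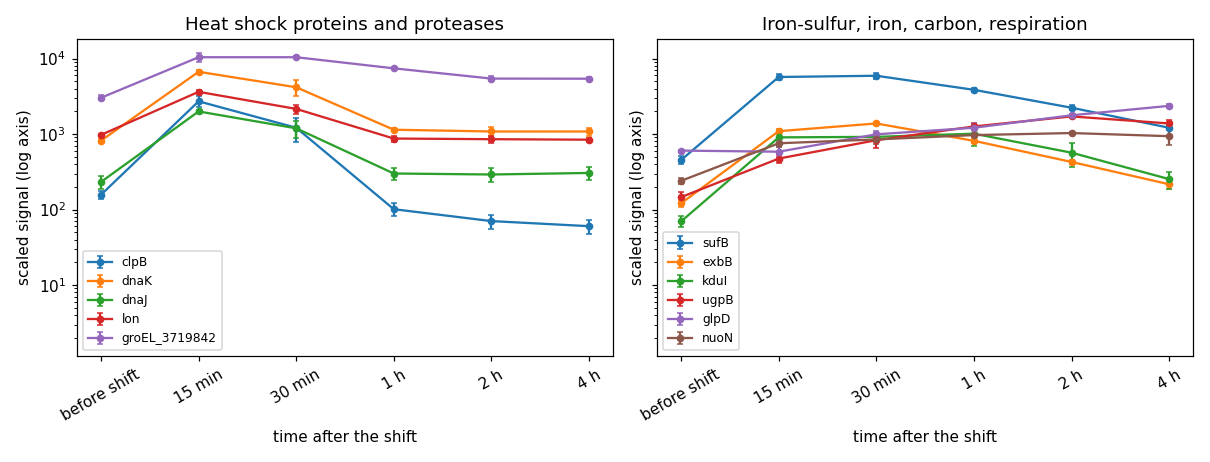
Scaled signal (y axis, log scale) by time after the shift (x axis) for heat shock genes and proteases (left) and genes of iron-sulfur assembly, iron uptake, carbon use and respiration (right); points are means and bars the SD of 4 arrays. clpB went from 157 to 2710 at 15 min and 60.2 at 4 h, sufB was at 5910 at 30 min and 1210 at 4 h, and glpD went from 603 to 2360.

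**Figure D4:**
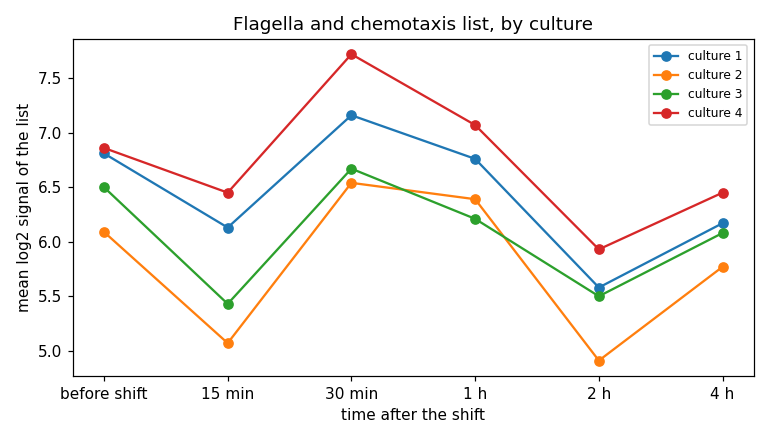
Mean log2 signal of the 19 genes of the flagella and chemotaxis list, all flagellar by symbol (y axis), by time (x axis), 1 line per culture. In each of the 4 cultures the mean fell to 15 min (by 0.40 to 1.07), rose to 30 min (by 1.03 to 1.47) and fell from 1 h to 2 h (by 0.71 to 1.48).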

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

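The tests of pufA in this part were chosen only after the result was seen; the search for arrays far from the others and the test of 4 h against 15 min were planned.

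In 23 of 338 groups of 4 arrays (6.8%, where chance gives about 5%), 1 array stood far from the other 3 in the level of a named gene or a list mean. The figure for each is the gap to the nearest other array as a share of the whole range. Culture 1 stood apart 4 times, culture 2 7 times, and cultures 3 and 4 6 times each. Before the shift these were bchE (0.933, culture 2 lowest), hemA (0.874, culture 1 lowest), hemF (0.873, culture 3 highest), gor (0.865, culture 1 highest), rpsP (0.862, culture 4 lowest), the heme synthesis list (0.854, culture 3 highest) and the citric acid cycle list (0.902, culture 2 highest). At 15 min they were uxaC (0.927, culture 2 highest), pufA (0.919, culture 1 highest), bchL (0.887, culture 3 lowest), dorR (0.885, culture 1 highest), atpD (4796502; 0.878, culture 3 highest) and the ATP synthase list (0.882, culture 4 lowest). At 30 min they were uxaC (0.86, culture 2 highest), the iron and manganese list (0.839, culture 2 highest) and the ribosomal list (0.833, culture 2 lowest). The oxidative stress list stood apart at 1 h (0.897, culture 2 highest) and at 4 h (0.91, culture 4 highest), and flgH at 2 h (0.894, culture 4 highest). At 4 h the others were fnrL (0.923, culture 3 lowest), sufB (0.923, culture 3 lowest), pufX (0.901, culture 4 highest) and phaC (0.871, culture 4 lowest).

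Of the 84 genes named for 15 min or 4 h against before the shift, 55 differed between 4 h and 15 min in a direct test of the difference. Of all 4281 probe sets 51.2% did, so such a difference was common at large. Genes named for other comparisons alone, such as mscL, were not part of this search. The values are log2 changes from 15 min to 4 h, and the median of all changes against before the shift lay at -0.15 at 15 min and 0.24 at 4 h. Photosynthesis transcripts that were lower at 4 h were pufM (-3.93), pufL (-3.81), puhA (-3.71), pufA (-3.23), pufX (-2.98), tspO (-0.91) and crtA (-0.45). So were the stress genes clpB (-5.50), dnaJ (-2.73), dnaK (-2.63), msrA (-1.84), chrR (-1.65), uvrA (-1.55), groEL (3719842; -0.94) and grxC (-0.76). Genes of iron, iron-sulfur and carbon use with lower levels were sufC (-2.34), exbB (-2.34), sufB (-2.24), uxaC (-2.03), exbD (-1.96), kduI (-1.85), pqqD (-1.18) and feoB (-1.12). Also lower were rpsU (-0.69), ccmD (-0.62), rplF (-0.44) and fumC (3719607; -0.42). Higher at 4 h were the glycerol and glycerol 3-phosphate genes glpD (2.03), glpK (1.93), ugpB (1.54), ugpA (1.48) and ugpE (1.05). Higher among genes of pigment, heme and isoprenoid synthesis were hemF (1.41), bchI (1.05), dxs (0.59), bchL (0.52) and hemA (0.44), and among regulators appA (0.87), ppsR (0.57) and fnrL (0.45). The other higher genes were fliN (1.31), bfr (3722043; 1.13), recA (0.93), atpD (4796502; 0.83), recQ (0.81), cbbX (0.76), cobO (0.70), cobS (0.65), hypF (0.57), fusA (0.51), gor (0.50), sdhA (3720729; 0.46), atpA (3719828; 0.36), clpX (0.34) and mdh (0.33). Among lists the difference passed for ribosomal proteins (adjusted p = 2e-11), photosynthetic complexes (1.3e-09), heat shock proteins (3.7e-09), iron and manganese (0.0014) and oxidative stress (0.032). For ribosomal proteins and oxidative stress the call was lost (adjusted p = 0.13 with an estimated correlation for each), oxidative stress was lost without culture 3 too (0.072), and the ribosomal direction turned with quantile normalization (0.66).

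At 15 min pufA kept a high signal while pufL and pufM of the same operon had fallen, and all 5 probe sets for pufA lay between -0.40 and -0.24 on the log2 scale. The change of pufA minus the mean change of pufL and pufM was 1.64 on average (SD 0.29, 1.42 to 2.05 over 4 cultures), pufA falling less in each culture. This difference restates what drew attention to pufA, so it decides nothing about scaling of whole arrays, which cancels from it by construction. A ceiling of the signal scale stays open: the brightest signal on an array was 1.39 times that of pufA, with 21 to 30 probe sets brighter, and a bright probe set may compress a fall. A slower loss of this part of the transcript could also give the pattern and stays open, with pufA still changing by -1.02 from 2 h to 4 h. These values cannot tell the 2 apart, and removal of light and entry of oxygen, which came together, were not tested singly.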

How the results depend on the processing

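All alternatives in this part were planned except those of the 17 added lists, which were chosen after the data were seen. Of 148 gene results, 143 were called, and 124 of these kept their direction and call under each alternative. Of 102 list results, 39 were called and 29 of these kept call and direction under each alternative. The 11 counts stayed within 1.5 times of the reported count under each alternative that kept all arrays or used only the 8 arrays compared. They moved further for the 4 steps between successive times when arrays were left out: 30 min against 15 min went to 251 to 441 of 463 (264, 303 and 251 without cultures 1, 2 and 3), 1 h against 30 min to 160 to 413 of 399 (162, 240 and 160 without cultures 1, 2 and 3, and 254 without the 30 min array of culture 3), 2 h against 1 h to 204 to 312 of 359 (204 and 208 without cultures 1 and 3) and 4 h against 2 h to 175 to 296 of 304 (175 and 177 without cultures 1 and 3). Fewer arrays leave fewer degrees of freedom in these fits. Culture as a block, with a consensus correlation of 0.0376 as a random effect, changed none of the calls of the 148 gene results and no list call other than that of the flagellar list at 4 h. Among list members outside those results it did change calls, such as 8 flagellar rises in place of 1 at 30 min, 11 flagellar falls in place of 7 at 15 min and 6 cobalamin falls in place of 4 at 15 min. Detection calls and background levels were not used here, so no limit for dim genes was set from signal over background.

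The following are adjusted p-values of lists, against before the shift unless stated, and the cause of each change was not tested. With an estimated correlation between genes these calls ended: ribosomal proteins at 15 min (0.061), 30 min (0.063), 1 h (0.12), 2 h (0.23), 4 h (0.43) and 4 h against 15 min (0.13), heat shock at 30 min (0.14), flagella at 2 h (0.6), cobalamin at 4 h (0.46) and oxidative stress for 4 h against 15 min (0.13). limma's fry, which asks whether a list changed at all and not whether it changed more than other genes, called lists that camera did not. At 15 min these were cobalamin (0.0029), ATP synthase (9.4e-06), oxidative stress (4e-06), iron and manganese (3.6e-14), hydrogenase (0.04) and flagella (0.048). At 30 min they were cobalamin (0.0017), ATP synthase (0.00016), cytochromes (0.02), citric acid cycle (0.0039), translation factors (2.8e-05), oxidative stress (0.028) and iron and manganese (4.7e-15). At 1 h they were cobalamin (0.011), ATP synthase (0.019), cytochromes (0.0037), translation factors (4.3e-05), iron and manganese (1.9e-12), hydrogenase (0.014) and DNA repair (0.023). At 2 h they were cobalamin (0.017), cytochromes (0.02), translation factors (0.0019), iron and manganese (4.4e-09) and DNA repair (7.5e-06), and at 4 h translation factors (0.0018) and DNA repair (1.4e-07). For 4 h against 15 min they were heme (6.2e-08), ATP synthase (0.00038), NADH dehydrogenase (0.0068), hydrogenase (0.0074), DNA repair (1.4e-08) and isoprenoid and quinone (5.9e-09). fry gave the opposite direction for cytochromes (0.59) and the citric acid cycle (0.25) at 15 min, heat shock (0.16) and flagella (0.78) at 1 h, and heat shock at 2 h (0.87). It did so too at 4 h for the citric acid cycle (0.19), oxidative stress (0.86), iron and manganese (0.0039) and hydrogenase (0.43), and for 4 h against 15 min for pigment synthesis (0.0062), cobalamin (0.51), citric acid cycle (0.017), translation factors (0.017) and flagella (0.34).

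Quantile normalization turned the direction of the citric acid cycle at 15 min (0.78), 4 h (0.76) and 4 h against 15 min (0.33), DNA repair at 15 min (0.88), flagella at 1 h (1), and, for 4 h against 15 min, ribosomal proteins (0.66) and translation factors (0.76). Median centring turned DNA repair at 15 min (0.91), flagella at 1 h (0.97), the citric acid cycle at 2 h (0.98) and, for 4 h against 15 min, pigment synthesis (0.98), NADH dehydrogenase (0.64) and flagella (0.92). Culture as a block turned flagella at 1 h (0.89) and for 4 h against 15 min (0.98), and called flagella at 4 h (0.02). Without the filter on dim probe sets flagella at 1 h (0.95), the citric acid cycle at 2 h (0.99) and iron and manganese at 4 h (0.99) turned. Leaving out 1 culture ended the call of cobalamin at 4 h (0.029 to 0.067, culture 2) and of oxidative stress for 4 h against 15 min (0.014 to 0.072, culture 3), and called flagella at 4 h (0.035 to 0.16, culture 2). It turned the direction of lists that were not called: citric acid cycle at 15 min (0.93 to 1), 1 h (0.82 to 0.99), 2 h (0.92 to 1) and 4 h against 15 min (0.94 to 0.97), DNA repair at 15 min (0.87 to 0.94), heat shock at 1 h (0.9 to 1), flagella at 1 h (0.87 to 0.99), hydrogenase at 4 h (0.83 to 0.94) and translation factors for 4 h against 15 min (0.72 to 0.91).

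Among genes, nifH, which was not called, turned its sign at 15 min with quantile normalization (0.04), median centring (0.08) and arrays left out (-0.29 to 0.13), and at 4 h likewise (-0.09, -0.03 and -0.19 to 0.40). rpoE at 4 h ranged from -0.35 to 0.06 with arrays left out, and at 15 min passed the test without the variance trend (adjusted p = 0.024) and without the array of culture 4 (0.027). The call of chrR at 4 h (0.49, adjusted p = 0.0058) ended with median centring (0.074) and without cultures 1 (0.12) and 2 (0.052). Calls that ended under some alternatives, beside those of pufA, fnrL, flgG, flgH, ugpA and kduI given with the results, were recA (without cultures 1, 2 and 3: 0.14, 0.1 and 0.054; both scalings: 0.092 and 0.49), recO (without cultures 2 and 3: 0.14 and 0.1; both scalings: 0.11 and 0.1), rpsU (without culture 1: 0.092; median centring: 0.058), nifS (without cultures 1, 2 and 3: 0.15, 0.13 and 0.09), dorR (without cultures 1 and 4: 0.085 and 0.17), dorS (without the 15 min array of culture 1: 0.055) and hypD (without culture 2: 0.065) at 15 min. At 4 h they were ccmB (without cultures 1, 2 and 3: 0.15, 0.073 and 0.14; both scalings: 0.12), grxC (without culture 3: 0.052), hypF (without culture 2: 0.089), hypD (without culture 4: 0.35) and fliE (without cultures 1, 2 and 3: 0.054, 0.21 and 0.081). Other single arrays left out also ended the calls of recA, recO, nifS, dorR, ccmB, hypF, hypD and fliE, with adjusted p between 0.05 and 0.19, as did only the 8 arrays compared for dorR (0.089) and no variance trend for fliE (0.053).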

Other observations

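The lists of this part, the test of list means over splits, the test of single cultures and the tests of rises and falls were chosen only after the result was seen; the counts over splits and the random lists were planned.

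Genes for glycerol use and sugar acid use rose beyond the fixed lists. The 5 genes for glycerol and glycerol phosphate rose in 3 of 5 members at 15 min (adjusted p = 0.046; 0.055 and 0.051 without cultures 2 and 4) and in 5 of 5 at 4 h (median 1.98, adjusted p = 0.00018). With an estimated correlation neither call held (adjusted p = 0.32 and 0.077 with an estimated correlation, the highest of the alternatives, whose lowest were 4.3e-06 and 2.3e-13). The 5 members are ugpA, ugpB, ugpE, glpD and glpK, which were already among the largest named rises at 4 h. The list was chosen after that was seen, so its p-value at 4 h decides nothing. The next 2 lists share this limit in part, as they hold uxaC, kduI and edd, and pqqD, which were named for their rises. Sugar acid and Entner-Doudoroff genes rose in 6 of 7 at 15 min (median 1.83, adjusted p = 3.2e-05, 0.039 with an estimated correlation) and in 6 of 7 at 4 h (median 1.79, adjusted p = 0.00034, adjusted p = 0.054 with an estimated correlation). From 15 min to 4 h that list fell in 3 of 7 (median -0.12, adjusted p = 0.017, adjusted p = 0.14 with an estimated correlation). The 4 genes of PQQ synthesis rose in 4 of 4 at 15 min (median 1.85, adjusted p = 0.0042, adjusted p = 0.077 with an estimated correlation) and fell in 4 of 4 from 15 min to 4 h (median -1.10, adjusted p = 0.0025, adjusted p = 0.072 with an estimated correlation). Phosphate and sulfate uptake rose in 6 of 7 at 15 min (median 1.36, adjusted p = 0.00051, adjusted p = 0.054 with an estimated correlation) and fell in 6 of 7 by 4 h (median -1.13, adjusted p = 3.9e-05, 0.039 with an estimated correlation).

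Lists of growth and biosynthesis were higher at some times. They hold named genes only, and of the 479 named genes kept more rose than fell at 15 min (189 and 128) and at 4 h (256 and 79). Aminoacyl-tRNA synthetases rose in 9 of 15 members with 1 fall at 15 min (median 0.44, adjusted p = 0.016, adjusted p = 0.16 with an estimated correlation) and in 14 of 15 at 4 h (median 0.72, adjusted p = 0.00042, adjusted p = 0.074 with an estimated correlation). Purine synthesis rose in 8 of 11 at 15 min (median 0.49, adjusted p = 0.0082, adjusted p = 0.13 with an estimated correlation) and in 9 of 11 at 4 h (median 0.70, adjusted p = 0.0034, adjusted p = 0.096 with an estimated correlation). Amino acid synthesis did not pass at 15 min (adjusted p = 0.17) and rose in 28 of 38 with 2 falls at 4 h (median 0.49, adjusted p = 0.0034, adjusted p = 0.054 with an estimated correlation). Protein export rose in 7 of 10 at 15 min (median 0.59, adjusted p = 0.0042, 0.046 with an estimated correlation) and did not pass at 4 h (0.67). From 15 min to 4 h it fell in 7 of 10 with 1 rise (median -0.52, adjusted p = 0.0025, 0.039 with an estimated correlation), a call lost with quantile normalization (0.074, the highest of the alternatives). In that direct test aminoacyl-tRNA synthetases (0.11), purine synthesis (0.42) and RNA polymerase (0.92) did not pass. Amino acid synthesis rose in 25 of 38 with 2 falls (median 0.46, adjusted p = 0.037, adjusted p = 0.1 with an estimated correlation), a call lost too with either scaling (0.13 and 0.31) and without cultures 1 (0.052) and 4 (0.053). RNA polymerase rose in 5 of 7 at 15 min (median 0.51, adjusted p = 0.04, adjusted p = 0.14 with an estimated correlation), a call lost too without cultures 3 (0.051) and 4 (0.053), with quantile normalization (0.089) and without the filter on dim probe sets (0.11). Lists for fatty acid synthesis (0.92 at 15 min, 0.76 at 4 h), cell wall and division (0.9 and 0.07), molybdenum (0.62 and 0.78) and thiamine (0.61 and 0.36) did not pass, and histidine, glycogen, inositol and choline genes were too few to test.

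At 15 min falls outnumbered rises, and at 4 h rises outnumbered falls. With median centring falls made up 45.5% of the calls at 15 min and 40.7% at 4 h. Centring shifts all log2 signals of an array by 1 amount, which moves these shares by itself. In the step from 30 min to 1 h it moved the share away from even, from 48.1% to 76.4%. The shares therefore decide nothing about the authors' scaling to a trimmed mean, which stays open at both times. The 3 probe sets for thrC of Bacillus subtilis, taken as spike controls, averaged 13710 before the shift (SD 1572), 11480 at 15 min (SD 2146) and 12900 at 4 h (SD 2303). Their log2 shifts against before the shift were -0.27, -0.26, -0.19, -0.07 and -0.10 in order of time. They were not used to set the scale, since the amount added is not stated and their signal before the shift exceeds that of pufA (12100), for which a ceiling was left open.

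The mean of the flagellar list went down to 15 min, up to 30 min and down from 1 h to 2 h, although against before the shift 7 of 19 members passed at 15 min and 1 of 19 at 30 min, and the list at neither (adjusted p = 0.3 and 0.47). A single culture is argued against, as 4 of the 4 cultures showed these 3 steps in the list mean. A drift shared by probe sets of this brightness is argued against too. Of 10000 random lists of the same size and brightness, none moved as far as 1.25 from 15 to 30 min (random mean 0.09, range -0.29 to 0.54). None moved as far as -1.13 from 1 to 2 h (0.05, -0.48 to 0.36). The share was 1e-04, the smallest that many lists can give. Random lists lack the correlation between flagellar genes (estimated at 0.5), so that share does not exclude chance for genes that vary together. The list and these steps were also singled out because the list moved there, which by itself makes the share small. What the random lists show is that other probe sets of this brightness did not move so on average. Of the 6 tested comparisons the list was called at 2 h alone (0.00022 with culture as a block, adjusted p = 0.6 with an estimated correlation), and with culture as a block also at 4 h (0.02). Light, oxygen and handling at the shift were not tested singly.

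Other splits of the 8 arrays of each comparison into 4 and 4 were set against the real split by their counts of probe sets. In each of the 10 comparisons 1 of 35 splits, the real one, gave a count as large. The highest other counts were 1 at 15 min (real 2288), 4 at 30 min (2168), 1 at 1 h (2126), 0 at 2 h (2181) and 44 at 4 h (2200). They were 6, 11, 1 and 8 for the 4 steps in order (463, 399, 359 and 304) and 195 for 4 h against 15 min (2192). Among the splits that part the 2 arrays of every culture the highest were 0, 1, 0, 0, 44, 2, 0, 0, 0 and 1. A share of 1 of 35 is the smallest these splits can give, and 1 of 8 among those that part the cultures. Other splits also leave the real change in the spread, which lowers their counts. By themselves the counts of probe sets therefore do not exclude chance. For the F test 1 of 100 splits gave a count as large (3016, highest other 4). For the number of called lists these splits do not exclude chance, and could hardly do so, since other splits keep part of the real change (up to 1.48 of 2.64 for the photosynthetic complexes at 15 min): at 15 min 8 of 35 splits called as many as the 7 lists of the real split (highest other 8), at 30 min 7 (7 lists, highest 8), at 1 h 9 (6, highest 7), at 2 h 11 (7, highest 8), at 4 h 11 (7, highest 8) and for 4 h against 15 min 9 (5, highest 6). Another split reached the mean change of 0 of the 39 called list results, which decides nothing, because these lists were chosen for being moved by the real split.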
